A study of Rattus norvegicus with 11 samples.

How the data were processed

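Gene expression was measured in 11 rat RNA samples, each on 1 array, with 1-colour Agilent arrays whose dye is given as Cy3 (the label protocol speaks of biotinylated cRNA). Per the labels, total RNA was extracted with Trizol, cleaned up and treated with DNase on columns, and cell lines were kept in RPMI medium with serum and G418. The deposited values are intensity values on a linear scale, normalized between arrays by the authors with a method that is not given in the sources used here. The values were checked: all are above 0, each is 2 to the power of a number rounded to hundredths, array medians lie between 156.5 and 165.4 (a range of 0.08 log2), and every array has the same highest value, 422913. Background correction and probe summary are also not given in the sources used here.

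Of 30367 probes, 20369 had a single gene symbol and 9998 had none in the platform's annotation. Symbols were updated with the RefSeq gene table of assembly GRCr8, used for names only: 17237 probes matched by RefSeq accession, 2569 by current symbol, 551 by a unique synonym, and 12 kept the symbol of the platform's annotation. No coordinates were used. Values were floored at the 1st percentile (62.25, log2 5.96), which raised 0.82% of them, and log2 transformed. Array medians differed by less than 0.1 log2, so no further normalization was applied. A probe was kept when its mean within-array percentile was above 50 in at least 1 of the 9 groups, which kept 18619 probes and removed 11748. Unnamed probes stayed in the fits and in probe counts. A gene with several probes was represented by the probe with the highest mean over the 11 arrays, which gave 11069 genes.

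The 9 groups were taken from the labels: endothelial cells (EC) as control, after AS exosomes and after ASTspan8 exosomes, endothelial fibroblasts (RF) under the same 3 conditions, RNA of ASTspan8 exosomes, and ASML cells as wild type and with CD44 knock-down. EC after ASTspan8 exosomes and the exosome RNA had 2 arrays each, and the other 7 groups had 1. Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. A fit of all 11 arrays with 9 group means, with 2 residual degrees of freedom, served EC after ASTspan8 exosomes against control and against AS exosomes, exosome RNA against ASML wild type, and the difference between EC and RF in the ASTspan8 effect. Single arrays were there assumed to vary like the duplicated groups. An additive fit of cell type and treatment on the 7 EC and RF arrays, with 3 residual degrees of freedom, served the treatment effects over both cell types and EC against RF. The p-values measure only the spread between these arrays, since nothing in the labels says whether duplicate arrays come from separate cultures. Comparisons of 1 array with 1 were not tested, and probes at least 2-fold apart were counted.

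20 gene lists were tested in the 8 tested comparisons with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists, which makes 160 list tests. They were exosome-activated endothelium (from what is known of endothelium treated with Tspan8-bearing exosomes), angiogenesis, endothelial, fibroblast, epithelial and leukocyte markers, tetraspanins and exosome machinery, integrins, matrix proteases, chemokines and cytokines, interferon response, cell cycle, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein and amino acid stress, immediate early genes, TGF-beta targets, histones, cytosolic ribosomal proteins and oxidative phosphorylation. No list passed in any comparison once camera estimated the correlation, a test that then has only the fit's residual degrees of freedom. In the 5 untested comparisons a list's median was ranked among 10000 random lists of the same size matched on expression in 20 bins, as a description. Random lists do not keep the correlation between the genes of a real list, which can make extreme percentiles frequent. In the outer 0.05 of random lists, both tails together, lay 10 of the 20 lists for AS exosomes in EC and 10 in RF. The number was 9 for ASTspan8 exosomes in RF, 9 for ASTspan8 against AS exosomes in RF and 6 for ASML. List members that rose or fell were counted over all genes tested and adjusted over the list alone.

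The named genes were the 10 with the largest positive and the 10 with the largest negative difference among genes past the threshold (at least 2-fold apart where fewer passed or no test was made), up to 4 members of each list with the largest difference, and always Tspan8, Cd44 and the exosome-activated endothelium list. The comparisons, filter, lists, naming rule and alternatives, except those said to be chosen later, were fixed before the data were examined. The alternatives were another normalization, no filter or a filter at the 75th percentile, trend and robust eBayes, other sets of arrays in the fit, the mean of a gene's probes, other fold thresholds, an estimated correlation, and leaving out each array in turn.

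The fits were tested on simulated data with 200 of 18619 probes changed. Of probes changed by log2 1, 2 and 4, the self-test recovered 40.3%, 88.1% and 92.4% for EC after ASTspan8 exosomes against control, 31.3%, 85.1% and 97% against AS exosomes, and 37.3%, 89.6% and 100% for exosome RNA against ASML wild type. For the difference between EC and RF it recovered 1.5%, 41.8% and 81.8%. Over both cell types it recovered 14.9%, 82.1% and 97% for ASTspan8 exosomes against control, 9%, 80.6% and 97% for AS exosomes against control, and 26.9%, 82.1% and 95.5% for ASTspan8 against AS exosomes. For EC against RF it recovered 53.7%, 97% and 98.5%. Of the probes called there, 11 of 158, 10 of 152, 12 of 163, 4 of 87, 6 of 135, 8 of 132, 5 of 141 and 6 of 172 were false, in the same order, a share above 0.05 in the first 3 comparisons and in AS exosomes against control over both cell types. With no change simulated, 0 probes passed in each of the 8 comparisons. The simulation gave each probe the same spread on every array, while the real EC and exosome pairs differed in spread (SD 0.144 and 0.395 log2). It also changed far fewer probes than passed in the 11-array fits. The rates therefore hold for that setting and do not test whether single arrays vary like the duplicated groups. MicroRNA was not analysed here, and no array was left out of the main comparisons. Figures were drawn with matplotlib 3.10.9.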

Results

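The arrays measured messenger RNA in rat cells treated with tumour exosomes, small vesicles that cells release, and in the exosomes and tumour cells themselves. AS is a rat pancreatic adenocarcinoma line and ASTspan8 is AS made to express tetraspanin 8, a membrane protein of exosomes. ASML is a rat pancreatic adenocarcinoma line used here as wild type and with CD44, an adhesion receptor, knocked down. EC are labelled endothelial cells and RF endothelial fibroblasts, although the source field of the RF control array names endothelial cell lines. There were 2 arrays of EC after ASTspan8 exosomes, 2 of ASTspan8 exosome RNA, and 1 of each of the other 7 groups. The number of arrays limits the precision, and a comparison of 1 array with 1 has no replicate check.

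Both recipient cells carried a fibroblast-type profile on these arrays. Of 28 fibroblast markers, 23 lay above log2 9 on the EC control array (list median 13.06) and 22 on the RF control array (median 13.63), against 6 on each exosome array and 4 in ASML wild type. Of 24 endothelial markers, 3 lay above log2 9 on the EC control array, 4 on the RF control array and 4 in ASML wild type. On the EC control array the junction proteins Cdh5 (7.87) and Pecam1 (7.50) lay below log2 9, and the receptors Kdr (6.52), Tek (6.10) and Tie1 (6.01) below log2 7. Of 27 epithelial markers, 21 lay above log2 9 in ASML wild type (median 12.72) and 3 on the EC control array. Of 20 leukocyte markers, between 1 and 3 did so on any array. Tspan8 itself was at 13.80 in ASML wild type and 13.06 in ASML with CD44 knock-down, at 10.28 and 10.16 in exosome RNA, and between 6.30 and 6.65 on all 7 EC and RF arrays, treated or not.

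**Figure D1:**
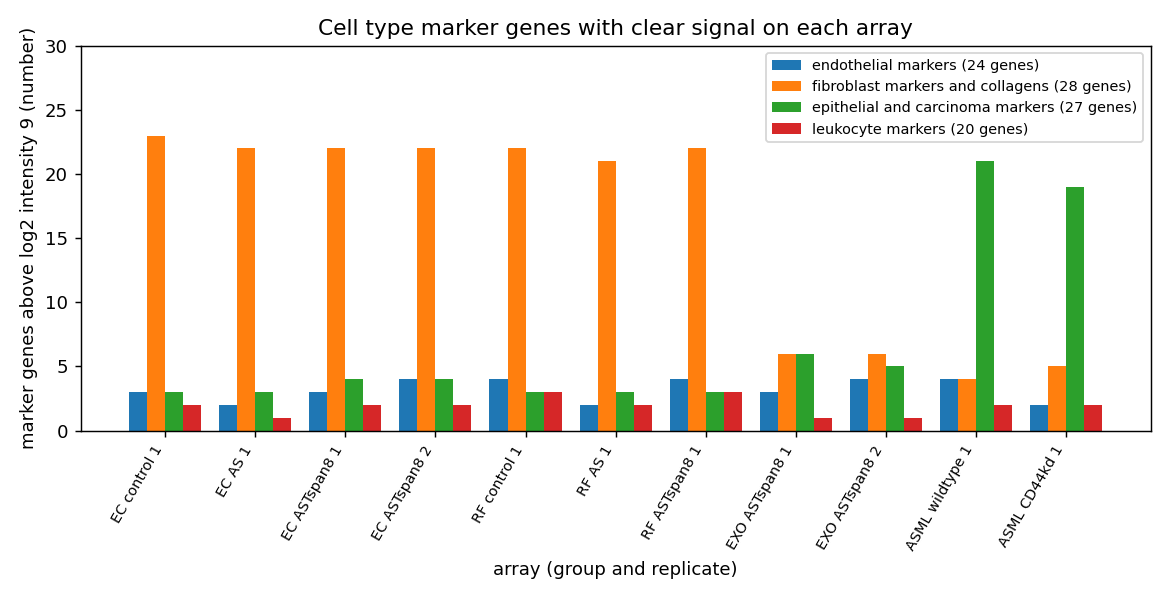
Number of marker genes above log2 intensity 9 on each of the 11 arrays, as bars for 24 endothelial, 28 fibroblast, 27 epithelial and 20 leukocyte genes. Fibroblast markers fill the EC and RF arrays (23 and 22 genes in the controls) and epithelial markers the ASML arrays (21 in the wild type).

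In the fit of all 11 arrays the duplicate arrays gave the spread against which changes were tested. In the additive fit of the 7 EC and RF arrays, that spread also held differences between EC and RF in their response to treatment. The EC pair differed with an SD of 0.144 log2 and had 9 of 18619 probes at least 2-fold apart. The exosome pair differed with an SD of 0.395 and had 358, among them the homeobox gene Rhox5 (16.49 against 11.32), Cd44 (11.11 against 6.02) and Thoc7 (11.73 against 6.77). Over probes the exosome pair had r = 0.99. That does not show the pair to be alike, since RF after AS exosomes and its control also had r = 0.99, with 403 probes at least 2-fold apart. The named genes with the largest differences, down to Zc3h14 (10.65 against 8.47), were all higher on the same array. RNA of another donor line or preparation on 1 of the arrays, or a technical difference between them, was neither shown nor excluded. This bears on the exosome mean, its Cd44 value and the pooled spread.

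The first question was what ASTspan8 exosomes change in EC. Interferon-induced antiviral genes rose most: Rsad2, an inhibitor of viral replication, by 2.96 ± 0.08 log2 (SE, n = 2 against 1; 11.23 against 8.27; adjusted p = 0.0146 by limma), Mx1, an antiviral GTPase, by 2.88 ± 0.13, and Isg15, a ubiquitin-like protein, by 2.55 ± 0.07. The transcription factor Fos fell by 5.46 ± 0.07 log2 (7.48 against 12.94; adjusted p = 0.00721), followed by the nuclear receptor Nr4a1 (-2.79), the phosphatase Dusp1 (-2.64) and the transcription factor Egr2 (-2.57). Outside these groups, the transcription factors Arid3a (2.26 ± 0.20) and Bcl11a (2.21 ± 0.07) rose, and Rgs2, a brake on G-protein signalling, (-2.35), the growth factor Areg (-2.10) and Hif1a, a hypoxia factor, (-1.96) fell. Ctnnal1 (2.49) and the folate carrier Slc19a1 (2.27) rose on the brighter of 2 probes, while the other probe gave 0.12 and 0.14.

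In all, 4492 of 18619 probes passed, 2255 higher and 2237 lower, and 621 of them changed at least 2-fold, 448 up and 173 down. By the brightest probe of each gene, 2890 of 11069 genes passed. The probe count moved to 1236 with no filter on dim probes and to 6800 with trend and robust eBayes. With either EC array after ASTspan8 exosomes left out 0 probes passed in limma, while 4381 to 4434 had an unadjusted p under 0.05, since the spread then came from the exosome pair alone.

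5 of the 20 lists differed from other genes in this comparison. The interferon list was higher (median 0.72, adjusted p = 2.79e-09; adjusted p = 0.238 with an estimated correlation): 20 of its 30 measured genes rose and 1 fell, or 25 and 1 adjusted over the list alone. Immediate early genes, which respond within minutes to stimulation, were lower (median -1.06, adjusted p = 2.69e-09; adjusted p = 0.238 with an estimated correlation), with 17 of 25 fallen and 1 risen, or 21 and 1 adjusted over the list alone. The single EC control array stood apart, with a list median of 12.56 against 10.27 to 11.49 on the other 6 EC and RF arrays. Unfolded protein and amino acid stress genes were lower (median -0.50, adjusted p = 3.15e-05 by camera; adjusted p = 0.372 with an estimated correlation). Of these, 12 of 25 had fallen and 2 risen, or 14 and 2 adjusted over the list alone. Among the fallen were the cystine carrier Slc7a11 (-1.43; 0.02 on its other probe) and the stress regulator Atf4 (-1.24). The AS array lay below the same single control for this list too (median -0.76), so a deviation of that control was not excluded. Histones were higher (median 0.95, adjusted p = 0.00689; adjusted p = 0.556 with an estimated correlation), with 11 of 18 risen, such as the linker histones H1f5 (2.01) and H1f4 (1.94), and 2 fallen, or 11 and 3 adjusted over the list alone. Ribosomal protein genes were lower by a small margin (median -0.20, adjusted p = 1.16e-05; adjusted p = 0.372 with an estimated correlation), with 18 of 72 fallen on either count.

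The exosome-activated endothelium list did not pass in EC (median -0.14, adjusted p = 0.442). Vcam1, an adhesion molecule for leukocytes, rose by 0.53 ± 0.09 (adjusted p = 0.0338), and the chemokine receptor Ccr1 fell by 0.52 ± 0.09 (adjusted p = 0.0326). The growth factor Vegfa gave -0.63 ± 0.07 (adjusted p = 0.0200) on its brightest probe, but its 4 probes ran from -0.63 to 1.00 and their mean gave 0.09 (adjusted p = 0.489). Mif (-0.14), Itgb4 (-0.05), Cd151 (0.04), Vwf (-0.37 on its brightest probe, with 3 probes from -0.37 to 0.97) and Tspan8 (0.05) did not pass. Cd44 gave 0.03 with an SE of 2.28, a spread set by the exosome pair. Among chemokines and cytokines 5 of 28 rose, such as Cxcl10 (1.57), which attracts T cells, and 8 fell, such as Il6 (-1.44), and the list did not pass (adjusted p = 0.841). Of 33 tetraspanin and exosome machinery genes 3 rose and 6 fell (adjusted p = 0.238), and of 26 matrix proteases and inhibitors 2 rose and 5 fell (adjusted p = 0.683).

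The second comparison set ASTspan8 against AS exosomes in EC, where other differences between the preparations and the single AS array are not separated from tetraspanin 8 on the donor cell. The complement genes C4a and Cfb were higher by 3.52 ± 0.13 and 3.12 ± 0.10 log2 (n = 2 against 1; each adjusted p = 0.0230 by limma), the iron-binding protein Lcn2 by 3.01 ± 0.07 and C3 by 2.14 ± 0.08. Much of this lay on the AS array: C4a stood at 12.71 in the control, 10.23 after AS and 13.75 after ASTspan8 exosomes, and Lcn2 at 12.27, 8.72 and 11.73. The antiviral genes Mx1 (2.61) and Rsad2 (2.43), the lipase inhibitor Angptl4 (2.58), the guidance factor Slit3 (2.36) and the chemokine Ccl19 (2.01) were higher too, Angptl4 with 13.53 in the control, 11.34 after AS and 13.92 after ASTspan8 exosomes. Mettl7b, a methyltransferase-like gene, (-3.52 ± 0.22 log2) and the transcription factor Six3 (-3.04 ± 0.12) were lower, at 9.67 and 9.20 after AS exosomes and near the floor after ASTspan8 exosomes and in the control (6.14 and 6.34). The mitosis gene Ckap2 fell by 1.33 ± 0.07. The endothelial adhesion protein Vwf was 1.19 ± 0.19 higher on its brightest probe (adjusted p = 0.0389; 3 probes from 0.04 to 1.19), on that probe again with a low AS array (8.88) and with 10.44 in the control against 10.07 after ASTspan8 exosomes. A second Vwf probe had no low AS array, with 8.94 in the control, 8.94 after AS and 9.95 and 9.88 after ASTspan8 exosomes. The dimmest gave 6.95, 7.32, and 7.41 and 7.31. In all, 2778 probes passed, 1403 higher and 1375 lower. 400 changed at least 2-fold, 351 up and 49 down. In limma 0 passed with either EC array after ASTspan8 exosomes left out (3538 to 3543 at an unadjusted p under 0.05), 0 with only the EC arrays in the fit (8294) and 0 with no filter on dim probes (6265).

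9 lists differed between the exosome types in EC. The interferon list was higher (median 0.50, adjusted p = 2.49e-07; adjusted p = 0.209 with an estimated correlation): 16 of 30 rose and 1 fell, or 17 and 1 adjusted over the list alone. Cell cycle genes were lower (median -0.58, adjusted p = 2.49e-07; adjusted p = 0.209 with an estimated correlation): 20 of 38 fell, such as the kinetochore gene Cenpf (-1.27; -0.31 on its other probe) and the cyclin Ccnb2 (-1.23), and 0 rose, or 25 fell adjusted over the list alone. Cholesterol biosynthesis was lower (median -0.40, adjusted p = 2.63e-06; adjusted p = 0.209 with an estimated correlation): 9 of 19 fell, such as Insig1 (-0.98) and Sqle (-0.97), or 13 adjusted over the list alone. For both lists the single AS array stood apart, with medians of 0.46 and 0.45 above control. ASTspan8 exosomes against control did not pass for them (-0.12, adjusted p = 0.30, and -0.02, adjusted p = 0.686). Histones were higher (median 0.81, adjusted p = 0.00464; adjusted p = 0.392 with an estimated correlation), with 11 of 18 risen and 1 fallen, or 11 and 3 adjusted over the list alone.

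Smaller shifts passed for 5 lists. Higher were TGF-beta targets (median 0.26, 5 of 22 risen, adjusted p = 0.0133), immediate early genes (0.19, 9 of 25 risen, adjusted p = 0.0325), angiogenesis genes (0.15, 5 of 27 risen, adjusted p = 0.0107) and integrins (0.13, 5 of 22 risen, adjusted p = 0.0429). Ribosomal protein genes were lower (-0.14, 4 of 72 fallen, adjusted p = 4.58e-04). Each of these 5 had adjusted p = 0.309 with an estimated correlation. Adjusted over the list alone, 5 TGF-beta targets, 9 immediate early genes, 7 angiogenesis genes, 5 integrins and 0 ribosomal protein genes moved that way. Against control TGF-beta targets (-0.03, adjusted p = 0.766), angiogenesis genes (0.20, adjusted p = 0.686) and integrins (0.13, adjusted p = 0.259) did not pass after ASTspan8 exosomes. TGF-beta targets stood at -0.20 on the AS array. The exosome-activated endothelium list did not pass (median 0.01, adjusted p = 0.880).

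**Figure D2:**
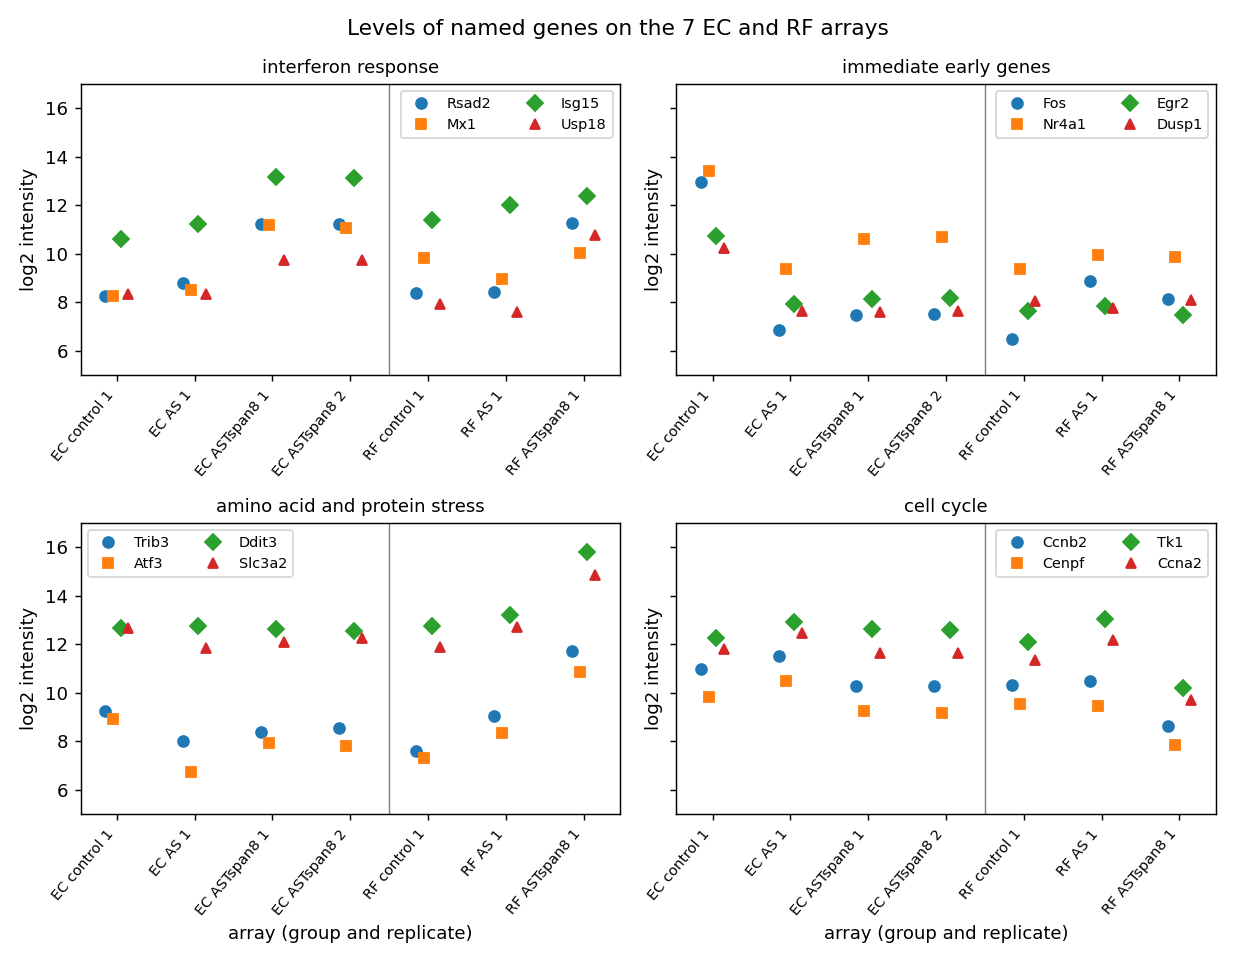
Log2 intensity of 4 genes each from the interferon, immediate early, stress and cell cycle lists on the 4 EC arrays (left of the line) and 3 RF arrays. Each point is 1 array, and Rsad2 stands at 11.23 (mean of the EC pair) and 11.25 (RF) after ASTspan8 exosomes against 8.27 and 8.37 in the controls.

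AS exosomes in EC were compared with control on 1 array each, so the values carry no test. Fos was lower by -6.09 log2 (6.85 against 12.94), Nr4a1 by -4.04, Lcn2 by -3.55, Egr2 by -2.80 and C4a by -2.48, while Mettl7b was higher by 3.53 and Six3 by 2.86. Of 18619 probes 18 were at least 2-fold higher and 191 at least 2-fold lower, against 9 between the EC duplicates and 358 between the exosome duplicates. Of 25 immediate early genes 14 were at least 2-fold lower (list median -1.30, percentile 0 among matched random lists), as were 6 of 25 stress genes (median -0.76, percentile 0), such as Atf3 (-2.15) and Asns (-1.68). Cell cycle (0.46), cholesterol biosynthesis (0.45) and interferon (0.25) medians were higher, each at percentile 100, with 0 members at least 2-fold apart. The control array of this comparison is also that of ASTspan8 exosomes against control, so both share its deviations.

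AS exosomes in RF were again compared with control on 1 array each. The proteoglycans Omd (-3.60), Aspn (-3.17), Lum (-2.15) and Dcn (-1.92) and the carboxylesterase Ces1d (-4.24) were lower, and the cytokine receptor Il1rl1 (2.40), Fos (2.37) and H1f4 (2.12) were higher. There were 183 probes at least 2-fold higher and 220 lower. Histones (10 of 18 at least 2-fold higher, median 1.21), stress genes (6 of 25, 0.71), cell cycle genes (2 of 38, 0.59), immediate early genes (7 of 25, 0.57) and hypoxia and glycolysis genes (4 of 28, 0.48) each stood at percentile 100. Fibroblast markers (6 of 25 at least 2-fold lower, median -0.16, percentile 2.05) and proteases (2 of 26, -0.26, percentile 0.12) stood low, as did the exosome-activated endothelium list (-0.30, percentile 0.78), and interferon genes stood at percentile 14.9 (-0.09).

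ASTspan8 exosomes in RF gave larger differences from control on 1 array each. Stress genes were among the highest: Gdf15, a stress cytokine, was higher by 4.43 (12.31 against 7.88), Trib3 by 4.13, the growth-arrest gene Gadd45g by 4.03, Atf3 by 3.54 and Ddit3 by 3.06. Rsad2 (2.88) and Usp18 (2.84), which trims Isg15 from proteins, were higher as well. Omd (-5.70), Ces1d (-4.73), Epyc (-4.62), Lum (-3.74), the collagens Col3a1 (-3.61) and Col1a1 (-2.26), and Vcam1 (-3.22) were lower. There were 863 probes at least 2-fold higher and 842 lower. At percentile 100 stood stress genes (14 of 25 at least 2-fold higher, median 1.19), histones (10 of 18, 1.13) and interferon genes (11 of 30, 0.56), and at percentile 0 stood cell cycle genes (23 of 38 at least 2-fold lower, -1.16) and fibroblast markers (11 of 25, -0.81).

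Against AS exosomes on 1 array each, ASTspan8 exosomes in RF gave higher Usp18 (3.17), Gadd45a (2.96) and Rsad2 (2.82) and the muscle-type oxidase subunit Cox6a2 (3.58), and lower Gins1 (-3.12), Pclaf (-3.10), Tk1 (-2.86) and Mcm3 (-2.55). There were 798 probes at least 2-fold higher and 1037 lower. Of 38 cell cycle genes 31 were at least 2-fold lower and all 38 were lower (median -1.64, percentile 0), and 9 of 30 interferon genes were at least 2-fold higher (median 0.78, percentile 100). Stress genes were higher (median 0.61, percentile 100). Hypoxia and glycolysis (-0.54, percentile 0), chemokines (-0.33, percentile 0.02), integrins (-0.29, percentile 0.01), oxidative phosphorylation (-0.26, percentile 0) and cholesterol biosynthesis (-0.38, percentile 0.51) were lower, with Ccl2 (-2.18) and Cxcl1 (-2.13) among the chemokines. Against control, hypoxia genes stood at 0.48 after AS and -0.13 (percentile 13.18) after ASTspan8 exosomes, and chemokines at 0.17 and -0.12 (percentile 6.26). A high AS array thus contributed to these differences. After ASTspan8 exosomes against control, integrins (-0.14, percentile 3.22), oxidative phosphorylation (-0.24, percentile 0.09) and cholesterol biosynthesis (-0.35, percentile 1.78) were low too.

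Effects averaged over both cell types were tested over the 7 EC and RF arrays, which does not test that an effect is common to both. Differences between EC and RF in the response count as residual spread there, so a low count of passing probes does not show a lack of response. For cell cycle genes after ASTspan8 exosomes, the median against control was -0.12 in EC and -1.16 in RF. Rsad2 rose after ASTspan8 exosomes by 2.90 ± 0.16 log2 (n = 3 against 2; adjusted p = 0.0390 by limma), the 1 probe to pass against control, and 2880 probes had an unadjusted p under 0.05. Isg15 (1.93 ± 0.39), Usp18 (1.96 ± 0.41) and Mx1 (1.75 ± 0.57) did not pass. Without the RF array after ASTspan8 exosomes 1712 probes passed, and 0 passed in limma without the EC control array (2959 at an unadjusted p under 0.05) or with either EC array after ASTspan8 exosomes left out (1440 to 1444). Without the RF control array 1 probe passed, a lower one, and Rsad2 did not (adjusted p = 0.311). Of the 5 arrays left out in turn Rsad2 passed only without the RF array after ASTspan8 exosomes (adjusted p = 0.0113). The interferon list was higher (29 of 30 genes positive, median 0.59, adjusted p = 7.60e-13; adjusted p = 0.329 with an estimated correlation), with 1 gene risen, or 16 adjusted over the list alone. Its median stayed between 0.55 and 0.79 and its call held with any of the 7 arrays left out. Leaving out either array after AS exosomes gave the same fit (0.59). The remaining AS array then has a term of its own and does not bear on this comparison. Without the RF array after ASTspan8 exosomes, all arrays after ASTspan8 exosomes are EC, so that fit does not describe both cell types. Histones were higher (median 0.94, adjusted p = 1.91e-04; adjusted p = 0.846 with an estimated correlation), with 8 of 18 risen adjusted over the list alone and 0 over all genes by limma. Cell cycle genes were lower (36 of 38 negative, median -0.46, adjusted p = 3.74e-07; adjusted p = 0.846 with an estimated correlation), a call lost without the RF array after ASTspan8 exosomes (-0.11, adjusted p = 0.391) and moved by its absence and by those of the control arrays (-0.74 without the EC control, -0.26 without the RF control).

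Between ASTspan8 and AS exosomes over both cell types, Rsad2 stood 2.61 ± 0.16 log2 higher (adjusted p = 0.0719), and 0 probes passed in limma, with 2835 at an unadjusted p under 0.05. Without the RF array after ASTspan8 exosomes 1116 passed. On this average all 38 cell cycle genes were lower (median -1.02, adjusted p = 2.85e-20 by camera; adjusted p = 0.661 with an estimated correlation), with 26 fallen adjusted over the list alone. In EC by itself 31 of the 38 were lower and 7 higher. The interferon list was higher (28 of 30 positive, median 0.52, adjusted p = 2.22e-11; adjusted p = 0.403 with an estimated correlation), with 12 risen adjusted over the list alone, and cholesterol biosynthesis was lower (median -0.46, adjusted p = 1.75e-06; adjusted p = 0.583 with an estimated correlation), with 3 fallen on that count. These 3 calls held with any array left out, at medians of -0.60 to -1.38 for the cell cycle (-0.60 without the RF array after ASTspan8 exosomes), 0.45 to 0.83 for interferon (0.83 without the EC array after AS exosomes) and -0.46 to -0.56 for cholesterol. Leaving out either control array gave the same fit, since the remaining control then does not bear on this comparison. Without the RF array after ASTspan8 exosomes, the effect of these exosomes rests on EC arrays only.

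After AS exosomes over both cell types 0 probes passed against control in limma, and 669 had an unadjusted p under 0.05. Averaged over both, all 38 cell cycle genes were higher (median 0.55, adjusted p = 1.78e-15 by camera; adjusted p = 0.574 with an estimated correlation). The median lay between 0.20 without the RF array after AS exosomes and 0.87 without the EC array after AS exosomes. It was 0.30 without the EC control. Histones (median 0.68, adjusted p = 6.57e-09; adjusted p = 0.574 with an estimated correlation) were higher, with the call lost without the RF control (0.43, adjusted p = 0.0997) and the median at 0.18 without the RF array after AS exosomes and 1.11 without the EC array after AS exosomes. Cholesterol biosynthesis (0.35, adjusted p = 5.05e-07; adjusted p = 0.574 with an estimated correlation) lost its call without the EC control (0.11, adjusted p = 0.0880). Hypoxia and glycolysis (0.25, adjusted p = 0.00774; adjusted p = 0.705 with an estimated correlation) lost its call without the RF control (0.07, adjusted p = 0.633) and turned to -0.08 without the RF array after AS exosomes, with 0.40 without the EC control and 0.52 without the EC array after AS exosomes. Proteases (-0.15, adjusted p = 0.00774; adjusted p = 0.574 with an estimated correlation) and fibroblast markers (-0.10, adjusted p = 0.0233; adjusted p = 0.705 with an estimated correlation) were lower, and without the RF control they gave 0 (adjusted p = 0.885) and 0.23 (adjusted p = 0.477), against -0.31 and -0.42 without the EC control. Proteases also lost the call without the RF array after AS exosomes (-0.12, adjusted p = 0.0958), and fibroblast markers without the EC array after AS exosomes (0, adjusted p = 0.494) or the RF array after ASTspan8 exosomes (-0.10, adjusted p = 0.0538), with -0.26 without the RF array after AS exosomes.

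**Figure D3:**
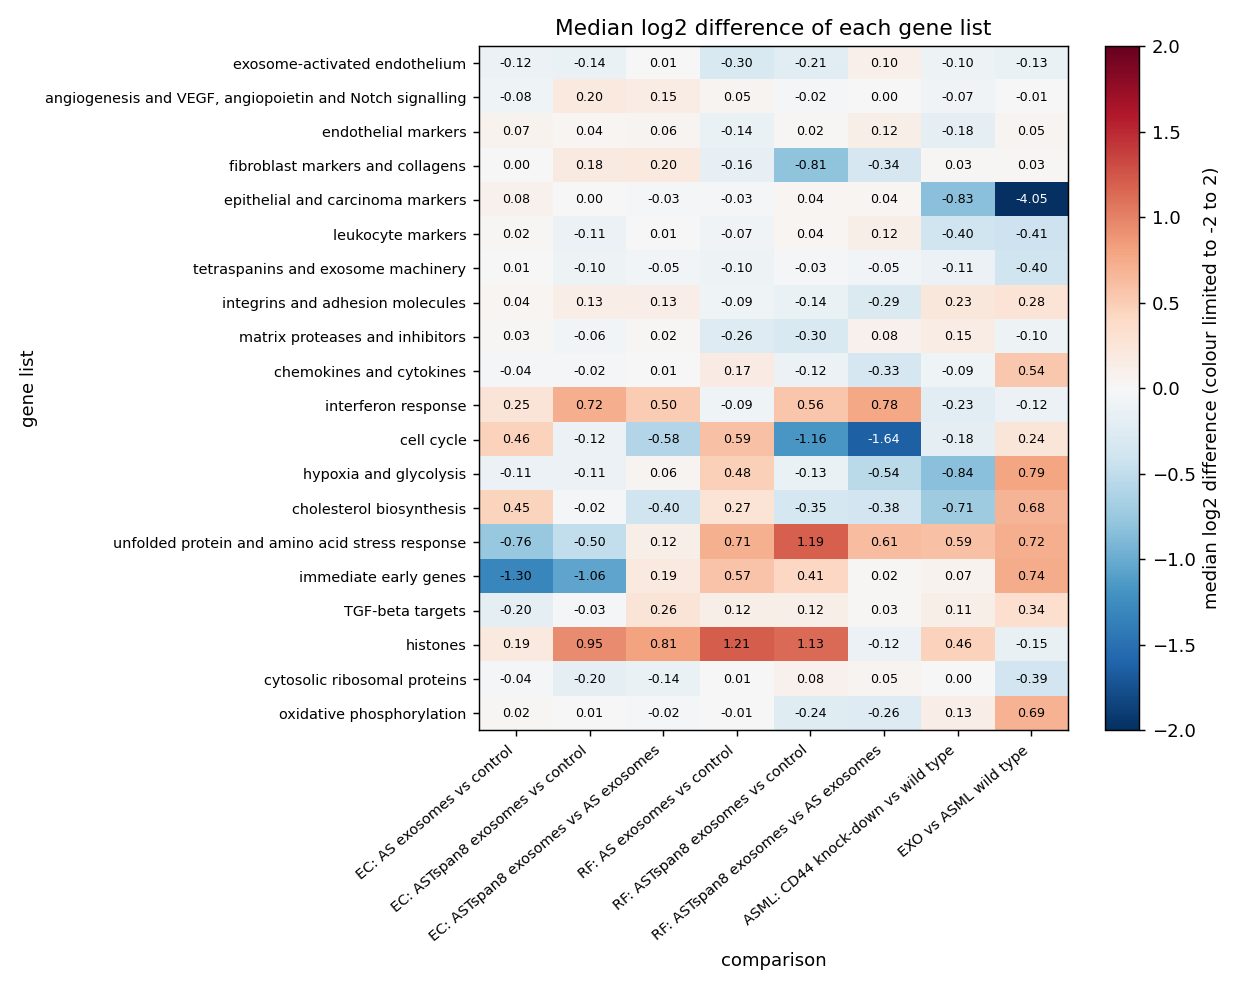
Median log2 difference of each of the 20 gene lists (vertical axis) in 8 comparisons (horizontal axis), as colour and printed value, with colour limited to -2 to 2. The interferon list is higher after ASTspan8 than AS exosomes in EC (0.50) and RF (0.78), and immediate early genes are lower than control in EC (-1.06) and higher in RF (0.41) after ASTspan8 exosomes.

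The difference between the EC and RF responses to ASTspan8 exosomes was tested with the spread of the duplicated groups, since 3 of its 4 groups had 1 array. The matrix proteoglycan Omd gave 6.15 ± 0.19 log2 (SE) and the esterase Ces1d 5.27 ± 0.15 more in EC than in RF, and Fos (-7.11 ± 0.11) and Gdf15 (-5.81 ± 0.12) less (each adjusted p = 0.00855 by limma). Of 18619 probes 5866 passed for this difference, and 0 passed in limma with either EC array after ASTspan8 exosomes left out (5624 to 5658 at an unadjusted p under 0.05). The interferon list did not pass for it (median 0.12, adjusted p = 0.448). Across the 11069 genes, which are not independent replicates, the responses against control had r = -0.03 (Spearman -0.02), against -0.08 for AS exosomes and 0.13 for ASTspan8 against AS exosomes, the 3 relations computed. Of 69 genes changed at least 2-fold in both cells after ASTspan8 exosomes, 32 went the same way. The same held for 9 of 37 after AS exosomes and 38 of 58 for ASTspan8 against AS exosomes.

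EC and RF themselves were compared over all 7 arrays to check the labels of the recipient lines. The retinoid carrier Crabp1 (5.94 ± 0.15 log2, n = 4 against 3, adjusted p = 4.05e-04 by limma), the stromal receptor Cd248 (5.81 ± 0.19), the fatty acid carrier Fabp5 (5.80 ± 0.27), the integrin Itgb1 (5.37 ± 0.27) and the surface protein Thy1 (2.79 ± 0.12) were higher in EC. The receptor Sirpa (-2.91; -0.43 on its other probe), the muscle-type genes Fhl1 (-2.71), Acta2 (-2.54) and Tagln (-1.64) and the matrix protein Postn (-2.08) were lower in EC. In all, 1587 probes passed, 947 higher and 640 lower. The count was 183 or 196 with an EC array after ASTspan8 exosomes left out, 578 without the EC or the RF control array, 619 without the EC or the RF array after AS exosomes and 2836 without the RF array after ASTspan8 exosomes.

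By list, cell cycle genes were higher in EC (median 0.92, 8 of 38 past the threshold, 25 adjusted over the list alone, adjusted p = 2.23e-11; adjusted p = 0.604 with an estimated correlation), as were hypoxia and glycolysis genes (0.68, 8 of 28, 15 over the list alone, adjusted p = 1.26e-07; adjusted p = 0.604 with an estimated correlation) and proteases (0.37, 4 of 26, 6 over the list alone, adjusted p = 0.00205; adjusted p = 0.604 with an estimated correlation). The exosome-activated endothelium list (0.53, 2 of 9, 4 over the list alone, adjusted p = 0.00464; adjusted p = 0.538 with an estimated correlation), with Itgb4 at 2.05 ± 0.18, and tetraspanins and exosome machinery (0.21, 8 of 33, 11 over the list alone, adjusted p = 0.00953; adjusted p = 0.538 with an estimated correlation) were higher too. Ribosomal protein genes were lower (-0.12, 0 of 72 by limma on either count, adjusted p = 0.0381; adjusted p = 0.832 with an estimated correlation). Endothelial markers (0.04, adjusted p = 0.506) and fibroblast markers (0.52, adjusted p = 0.189) did not pass.

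Exosome RNA was compared with ASML wild-type cells, a different donor line, so the differences join line and compartment. The secreted proteins Sostdc1 (9.75 ± 0.07 log2; 16.08 against 6.33; n = 2 against 1; adjusted p = 7.08e-05 by limma), Lcn2 (9.53 ± 0.07) and C1s (9.46 ± 0.07), the chemokine Ccl2 (8.67), the matrix protease Mmp14 (8.64) and Vcam1 (6.77) were higher in exosome RNA. The epithelial genes Krt18 (-10.25 ± 0.07), Cldn3 (-9.43 ± 0.22), Cdh1 (-8.20 ± 0.10) and Epcam (-8.01 ± 0.18) were lower, as was Tspan8 (-3.58 ± 0.09; 10.22 against 13.80). Cd44 (-5.00 ± 2.28, adjusted p = 0.130) did not pass, since the exosome arrays disagreed. Vwf gave 1.03 on its brightest probe and -0.96 as the mean of 3 probes, each past the threshold. In all, 12210 probes passed, 5234 higher and 6976 lower, around a median of -0.16 over all probes, and 6077 differed at least 2-fold.

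All 25 measured epithelial markers were lower in exosome RNA and past the threshold (median -4.05, adjusted p = 3.80e-09; adjusted p = 0.364 with an estimated correlation). Oxidative phosphorylation genes were higher (median 0.69, 57 of 86 risen and 9 fallen, adjusted p = 4.43e-06; adjusted p = 0.364 with an estimated correlation), and ribosomal protein genes lower (-0.39, 48 of 72 fallen and 1 risen, adjusted p = 3.33e-05; adjusted p = 0.364 with an estimated correlation). Stress genes (0.72, 16 of 25 higher, adjusted p = 0.00794), cholesterol biosynthesis (0.68, 13 of 19, adjusted p = 0.0213), each with adjusted p = 0.364 with an estimated correlation, and hypoxia and glycolysis (0.79, 19 of 28, adjusted p = 0.0125; adjusted p = 0.400 with an estimated correlation) were higher. Adjusted over the list alone the counts were 25 epithelial, 57 oxidative phosphorylation, 49 ribosomal, 18 stress, 13 cholesterol and 19 hypoxia genes. Interferon genes went both ways (12 higher, 12 lower, adjusted p = 0.821), and leukocyte markers did not pass (median -0.41, adjusted p = 0.434).

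In ASML cells with CD44 knock-down Cd44 was at 12.30 against 13.56 in the wild type, a difference of -1.26 log2 on its brightest probe with 1 array each, and 0.12 as the mean of its 4 probes. That mean gives equal weight to probes below log2 9. They stood at 8.79 against 8.28, 8.77 against 7.43, and 5.96 against 6.07 in the wild type. The connexin Gja1 was higher by 7.45, the lipid receptor Cd36 by 7.27, the mucin-type protein Pdpn by 6.71, the cadherin Cdh6 by 6.42 and the collagen Col6a1 by 5.92. Phactr1, an actin regulator, (-5.93), the neurotrophic factor Nrtn (-5.42), the lipid carrier Spns2 (-5.08) and the cadherin Cdh16 (-4.73) were lower, as were the epithelial splicing factor Esrp1 (-3.52) and Krt18 (-2.33). There were 1797 probes at least 2-fold higher and 1746 lower. Fibroblast markers and collagens stood at percentile 63.9 (median 0.03, 5 of 25 at least 2-fold higher). Epithelial markers (10 of 25 at least 2-fold lower, median -0.83) and hypoxia and glycolysis genes (11 of 28, -0.84), such as Adm (-3.08) and Hk2 (-2.23), stood at percentile 0, cholesterol biosynthesis at percentile 0.06 (-0.71), and stress genes (10 of 25 at least 2-fold higher, 0.59) at percentile 99.9.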

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

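In this part, the tests on carried-over RNA by share of the exosome level, on a response shared by both cells, on the EC control array, on suppression in every recipient and on marker levels were chosen after the result was seen.

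The difference between EC and RF in the effect of ASTspan8 exosomes passed limma's test of the difference itself for 5866 probes. The largest differences towards a more positive effect in EC than in RF were those of Omd (6.15), Ces1d (5.27), Aldh3a1 (4.57), Eln (4.46), Aoc3 (4.18), Aspn (4.12), Sfrp2 (4.03), Col3a1 (3.96), Ces1a (3.91) and Epyc (3.85). Those towards a more negative effect were Fos (-7.11), Gdf15 (-5.81), Trib3 (-4.90), Gadd45g (-4.82), Ppp1r15a (-4.67), Atf3 (-4.57), Mthfd2 (-4.30), Ciart (-4.27), Slc7a5 (-3.82) and Cox6a2 (-3.72).

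By list, the difference was positive for cell cycle genes (median 1.02, 26 of 38 past the threshold that way and 27 adjusted over the list alone; adjusted p = 2.42e-07; adjusted p = 0.232 with an estimated correlation) and for fibroblast markers and collagens (0.80, 13 of 25 and 15; adjusted p = 6.38e-05; adjusted p = 0.286 with an estimated correlation). It was also positive for integrins (0.56, 10 of 22 and 12; adjusted p = 0.00825; adjusted p = 0.286 with an estimated correlation) and oxidative phosphorylation (0.32, 27 of 86 and 30; adjusted p = 0.0186; adjusted p = 0.531 with an estimated correlation). It was negative for immediate early genes (-1.89, 18 of 25 and 21; adjusted p = 4.21e-08; adjusted p = 0.232 with an estimated correlation), stress genes (-1.66, 18 of 25 and 19; adjusted p = 1.69e-07; adjusted p = 0.272 with an estimated correlation) and ribosomal protein genes (-0.28, 18 of 72 and 16; adjusted p = 5.14e-05; adjusted p = 0.286 with an estimated correlation). In limma 0 probes passed with either EC array after ASTspan8 exosomes left out (5624 to 5658 at an unadjusted p under 0.05). Each control and the treated RF cells had 1 array, so a deviation of a single array and a difference between the cell types could not be separated by this test.

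Interferon genes were higher after ASTspan8 than AS exosomes in EC and RF. From AS to ASTspan8 exosomes the 30 interferon genes gained a median of 33.8% of their level in exosome RNA in EC and 49.6% in RF. The 95% intervals over genes were 13.4 to 50.6 and 8.2 to 104.8. The 93 exosome-specific transcripts gained 0% (-0.1 to 0 and 0 to 0.1). RNA of AS exosomes was not measured, and transcripts carried by both preparations would cancel here, so this share cannot decide on carried-over RNA. Against control the 93 transcripts rose no more than 428 genes low in exosomes and cells. The excess was -0.01 log2 in EC (95% interval over genes -0.04 to 0.04) and 0 in RF (-0.06 to 0.03). These values argue against RNA carried over from the added exosomes at a level the arrays detect. All these intervals resample genes on the same arrays, so they hold no spread between arrays, and RF had 1 array per condition. An overall shift remaining between the deposited arrays is argued against, since the lowest list median over both cells and both other normalizations was 0.46. The deposited arrays already had near-equal distributions (largest gap at the same rank 0.29 log2), so rescaling could change little. A distortion made by the authors' own normalization was therefore not tested. Whether the cells share the response stays open: 21 of 30 genes were higher in both, between the bounds set for it, and tetraspanin 8 on the donor cell and any other difference between the exosome preparations may each account for it, untested.

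Immediate early genes were lower after both exosome types than on the EC control array. In RF the lower of the list medians after AS and ASTspan8 exosomes was 0.41, above control. Both were taken against the single RF control array, whose list median (10.27) was the lowest of the 7, so a suppression by exosomes in every recipient was not excluded. The EC control array held the highest of the 7 values for 15 of 25 genes, and the highest of the 4 EC values for 22, which largely restates the pattern. A stimulated state of that 1 culture or sample and an effect of exosomes, in EC alone or in both cells, therefore stay open, since each cell type had 1 control array.

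The arrays labelled endothelial had low endothelial and high fibroblast markers. 21 of 28 fibroblast markers lay above log2 9 on both the EC and the RF control array, which is consistent with a shared fibroblast-like profile of both lines. Endothelial probes that do not respond could not be excluded, since 8 of 24 endothelial markers exceeded log2 9 on at least 1 of the 11 arrays and no array here is a known endothelial reference. Among the most abundant, Bgn stood at 18.31 and Col1a2 at 17.16 on the EC control array, and whether the cells lost endothelial markers in culture or were of another type was not tested.

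For the EC against RF count of 1587 probes, 3 of the 34 splits of the 7 arrays into 4 and 3 that could be fitted gave as many, the real one included, with a highest other count of 1937. Both other splits put the control arrays together in 1 group and the AS arrays together in the other. With the treatment term they are the same fit and estimate EC against RF after ASTspan8 exosomes alone. Differences between EC and RF on the control and AS arrays then count as residual spread. These splits therefore share only part of the real contrast and are no measure of a random grouping. All remaining splits gave 0 in limma, although the share of splits as planned does not exclude chance.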

How the results depend on the processing

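In this part the list tests without each array over both cell types were chosen after seeing the data. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.

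Counts past the threshold kept within 1.5 times their value under both other normalizations, except that quantile normalization left 0 probes in limma (2872 at an unadjusted p under 0.05) for ASTspan8 exosomes against control over both cell types (Rsad2 then had adjusted p = 0.0586). The split of ASTspan8 against AS exosomes in EC went from 1403 higher and 1375 lower to 1073 and 1497 with a common 75th percentile.

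With no filter on dim probes more probes were tested, and the counts were 1236 for ASTspan8 exosomes against control in EC, 0 against AS exosomes in EC (6265 at an unadjusted p under 0.05), 3404 for the difference between EC and RF and 0 over both cell types against control (3900). The filter at the 75th percentile, which tests fewer probes, gave 4710 for ASTspan8 against AS exosomes in EC, 784 for EC against RF, 136 for AS exosomes in EC and 2317 for ASML. Trend and robust eBayes gave 6800 and 5851 for ASTspan8 exosomes in EC against control and against AS exosomes. With only the EC arrays in the fit, 1 residual degree of freedom, ASTspan8 against AS exosomes gave 0 in limma (8294 at an unadjusted p under 0.05). All 11 arrays in the fit gave 2 and 2 over both cell types against control and against AS exosomes. The cause was not tested beyond these constructions.

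Requiring a 2-fold change as well left, by construction, 621 and 400 probes in EC against control and AS exosomes, 6077 for exosome RNA, 2671 for the difference between EC and RF and 623 for EC against RF. The mean of a gene's probes counts genes in place of probes and gave 7590 for exosome RNA, 3853 for the difference between EC and RF, 972 for EC against RF, 1 for ASTspan8 against AS exosomes over both cell types, 125 for AS exosomes in EC, 225, 1086 and 1003 in RF for AS exosomes, ASTspan8 exosomes and ASTspan8 against AS exosomes, and 2076 for ASML. In that order a 1.5-fold threshold gave 898, 2010, 5171, 4986 and 7324 probes, and the 99th percentile of the EC duplicate difference gave 1877, 3820, 7415, 7120 and 9591.

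Leaving out an array gave 0 to 0 probes in limma for ASTspan8 exosomes in EC against control (4381 to 4434 at an unadjusted p under 0.05), against AS exosomes (3538 to 3543) and for the difference between EC and RF (5624 to 5658), because 1 residual degree of freedom from the exosome pair then remained and the lone EC array was assumed to vary like it. It gave 0 to 1712 over both cell types against control and 0 to 1116 against AS exosomes, the highest without the RF array after ASTspan8 exosomes, and 183 to 2836 for EC against RF. For exosome RNA it gave 12491 to 13070, and for AS exosomes over both cell types 0 to 0 (444 to 1607 at an unadjusted p under 0.05). With an estimated correlation 0 lists passed in camera in each of the 8 comparisons. That test has 2 or 3 degrees of freedom, and its correlation also exceeded the preset 0.01 for some lists (0.58 for cell cycle genes and 0.39 for histones over the 7 arrays). In EC after ASTspan8 exosomes against control it lay below 0.01 for immediate early genes (-0.031) and interferon genes (0.0093). A higher correlation is thus argued against for the loss of those calls. For lists above 0.01 the causes were not separated.

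Reversed results were Vegfa in EC after ASTspan8 exosomes (0.09 with the mean of its probes), Vwf in exosome RNA (-0.96) and Cd44 in ASML (0.12), each because its probes differ in sign or size, and 3 lists after AS exosomes over both cell types: hypoxia and glycolysis without the RF array after AS exosomes (-0.08, adjusted p = 0.0206), and proteases (0) and fibroblast markers (0.23) without the RF control, where the cause was not tested. With an array left out these 3 medians ran from -0.08 to 0.52, from -0.31 to 0 and from -0.42 to 0.23. Of 6691 values of named genes under the alternatives named in the processing summary, 5767 stayed, 835 no longer passed, 29 newly passed, 57 moved and 3 reversed. In tested comparisons a gene that missed the threshold both before and after counted as stayed, whatever its change. The number that stayed is therefore no measure of how many calls held. Of those that no longer passed, 609 came with an array left out, 115 with no filter and 85 with only the arrays of the comparison in the fit.

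Signal over background limits the low end: log2 7 was taken as near background, and values close to the floor of 5.96, such as Six3 and Mettl7b in EC after ASTspan8 exosomes, make a fold a compressed estimate.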
